A study of Homo sapiens with 6 samples.

How the data were processed

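Messenger RNA was sequenced from PC-3 cells, per the labels, in 3 control libraries and 3 libraries of cells kept in 5 µM cepharanthine hydrochloride until day 3. Per the labels' protocols, cells grew in DMEM with 10% fetal bovine serum, RNA was extracted with TRIzol, and libraries were made from 1.2 µg of total RNA with a SMARTER mRNA-Seq kit. The control columns carry other names in the table than in the labels and were matched by group and number.

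The deposited table held, for 38843 genes, raw read counts and FPKM in every library. The count columns, so named per the file headers, held whole numbers with a different total in each library. The FPKM columns, also per the file headers, held non-integer values, and the gene length and total behind them are not given in the sources used here. The submitters' processing notes name the genome builds GRCm38, mm10 and hg38 without giving their roles. Gene identifiers and coordinates were compared with GENCODE 29 on GRCh38: 96.8% of the identifiers were in it, and of these 99.9% were on the same chromosome and 99.9% overlapped the same gene, with 87.6% sharing a start or an end. Coordinates are therefore those of the deposited table, in GRCh38. The aligner, the counting tool, its use of strand and the annotation release are not given in the sources used here.

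Raw counts were the unit of the tests. Genes were filtered with filterByExpr, which kept 21965, scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) between the 3 treated and 3 control libraries, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic. Means and SDs are of CPM over the 3 libraries of a group. Where a group had 0 counts, the fold is given as a bound with 3 counts over that group. In libraries of this depth, 28860, 28944 and 28321 control and 28373, 28069 and 29388 treated genes had a count above 0.

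Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists with at least 3 members tested. Camera with an estimated correlation and fry were alternatives. Members past the threshold were counted with p adjusted over all genes and with p adjusted over the list alone. Lists of marker genes for other cell types and of nuclear-retained RNAs were given as values only.

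The tests, the 27 lists, the naming rule and the alternatives were written before the data were examined. The rule named the 12 genes with the largest rise and the 12 with the largest fall past the threshold with all 3 values of a group above the other, up to 4 members of each list with the smallest adjusted p, and DUSP1, EGFR, MAPK3, CDKN1A, SQSTM1, MKI67 and the PC-3 identity genes. Some genes that it gave are not reported here. The others were 135 genes, of which 133 passed the threshold, and examples were taken from them. Exceptions chosen after their values were seen were GAA, ATG12, ATG16L1, CHAC1, CDC6, GINS3, CDC25C, IL1B, OAS1, DDX58, IFIT2, PFKM, SDHA, NPM1, FBL, ISY1, RAB43, the transcripts of the mitochondrial genome and the genes of the closing part. KEGG pathway membership was that of the deposited annotation, and camera was run on the 307 pathways with 10 to 300 members tested after the lists had been seen. A pathway may share members with a list, and the overlap was not counted. Its call in the same libraries is therefore not separate support for the list.

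Alternatives were DESeq2 1.42.0, edgeR with RLE factors, edgeR without a filter, a block on replicate number, each library left out in turn, and limma on log2(FPKM + 1) of genes with a mean FPKM of at least 1, with other pseudocounts, filters and scalings. After the values were seen, fits without mitochondrially encoded genes and of genes free of same-strand overlap were added.

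The tests were run on simulated data with known changes. The edgeR test recovered 24.2%, 58.7% and 76.2% of genes changed 1.5, 2 and 4 times, with 6.25% of its calls false. These were 66, 63 and 63 of 21220 genes, a far smaller share than the 27.9% called in the data. The adjusted threshold was therefore stricter in the simulation, and recovery may be understated. Counts were drawn with the dispersions of the edgeR fit, which is not neutral between the tests. DESeq2 recovered 40.9%, 65.1% and 88.9% with 27.2% false, and limma on log2(FPKM + 1) 28.6%, 79.1% and 88.4% with 7.61% false. Without a planted change edgeR called 0 genes. Camera called a planted list of 25 genes (adjusted p = 1.4e-14 with the preset correlation and 0.0177 with an estimated one) and 0 of 20 unchanged lists. Genes were simulated independently of each other, so this does not show how the preset correlation serves lists whose members are correlated. Correlations of log2 CPM between libraries of a group were 0.970 to 0.974 and between groups 0.954 to 0.961.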

Results

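The series measured messenger RNA by sequencing in PC-3, an established androgen-independent cell line from a metastasis of a human prostate cancer. Cells were grown with or without 5 µM cepharanthine hydrochloride, the salt of a plant bisbenzylisoquinoline alkaloid, and were collected on day 3. Each group held 3 libraries. Total counts were 55351436, 59241954 and 52774506 in the control libraries and 57971202, 53017816 and 68241156 in the treated libraries, and the group means did not differ by more than the spread (exact two-sided permutation p = 0.6, where 0.1 is the smallest p that 3 against 3 can give). A gene without any count is bounded at 3 counts, or 0.0440 to 0.0568 CPM (counts scaled to library size) depending on the library, and such floors and intervals cover counting error only. The labels do not say whether libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

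The comparison of treated with control cells asked which transcripts change under the compound, in a study of how it acts against prostate cancer. Treated cells held more transcript of SQSTM1, the autophagy receptor p62, which rose from 645 ± 38.9 to 1752 ± 80.2 CPM (SD, n = 3 per group), and of NPC1, the lysosomal cholesterol exporter, which rose from 411 ± 18.5 to 1048 ± 22.3 CPM. The stress factor DDIT3 (CHOP) rose from 69.9 ± 5.75 to 303 ± 85.1 CPM, and the endoplasmic reticulum chaperone HSPA5 (BiP) from 2752 ± 185 to 5503 ± 478 CPM. Transcripts of the matrix protein FN1 (fibronectin) fell from 3265 ± 355 to 916 ± 95.8 CPM, those of the replicative helicase subunit MCM3 from 50.1 ± 4.82 to 23.4 ± 2.32 CPM, and those of the mitochondrially encoded MT-CO1 from 27507 ± 5256 to 12809 ± 2173 CPM. These 7 genes had edgeR adjusted p between 2.8e-06 and 6.0e-04. SQSTM1 (ENSG00000161011) lies on chromosome 5 from 179806398 to 179838078, FN1 (ENSG00000115414) on chromosome 2 from 215360440 to 215436073, and MCM3 (ENSG00000112118) on chromosome 6 from 52264014 to 52284881, in GRCh38.

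Of 21965 genes tested, 3219 were higher and 2902 lower with cepharanthine (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 478 and 777 of them differed by a log2 fold change of 1 or more. In 6061 of the 6121 genes called, all 3 values of a group lay above all 3 of the other, which 43.4% of the tested genes did and 10% do by chance. Of these calls 52.6% were higher. In limma fits of 13451 genes, which differ from this test in unit and filter as well, the split moved with the scaling. It was 62.8% higher on FPKM as deposited (3208 higher, 1897 lower), 49.4% with median-ratio scaling (2681 and 2743), 50.8% after quantile normalization (2734 and 2653) and 83.5% after rescaling to TPM (4928 and 976). Between these fits rescaling to TPM moved the median log2 fold change of all genes from 0.07 to 0.26, and the members called higher from 11 to 18 in the lysosome list, 13 to 20 in the endoplasmic reticulum list, 8 to 14 in the EGFR, RAS and ERK list, 7 to 13 in the oxidative phosphorylation list and 11 to 23 in the ribosomal protein list. Of 27 gene lists fixed in advance, 19 passed camera with its preset correlation, 16 higher and 3 lower. With an estimated correlation camera called 0 lists, 8 of them had an unadjusted p under 0.05, and the lowest adjusted p was 0.116. The estimate was below the preset 0.01 for lysosome (0.0067), autophagy (-4.0e-05), EGFR-RAS-ERK components (-0.012) and NRF2 targets (-0.025). A higher correlation therefore did not end the calls of these lists. For autophagy the unadjusted camera p went from 2.6e-06 to 0.00636 at an estimate near the preset, so the setting changed more than the correlation. The adjusted p with an estimated correlation given below is therefore not a measure of correlated members alone. For ribosomal proteins it reached 0.565. Fry, which tests whether the members of a list move on balance in a direction, called 19 lists, 17 of them among the camera calls. Log2 fold changes below are treated over control with their SE.

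**Figure D1:**
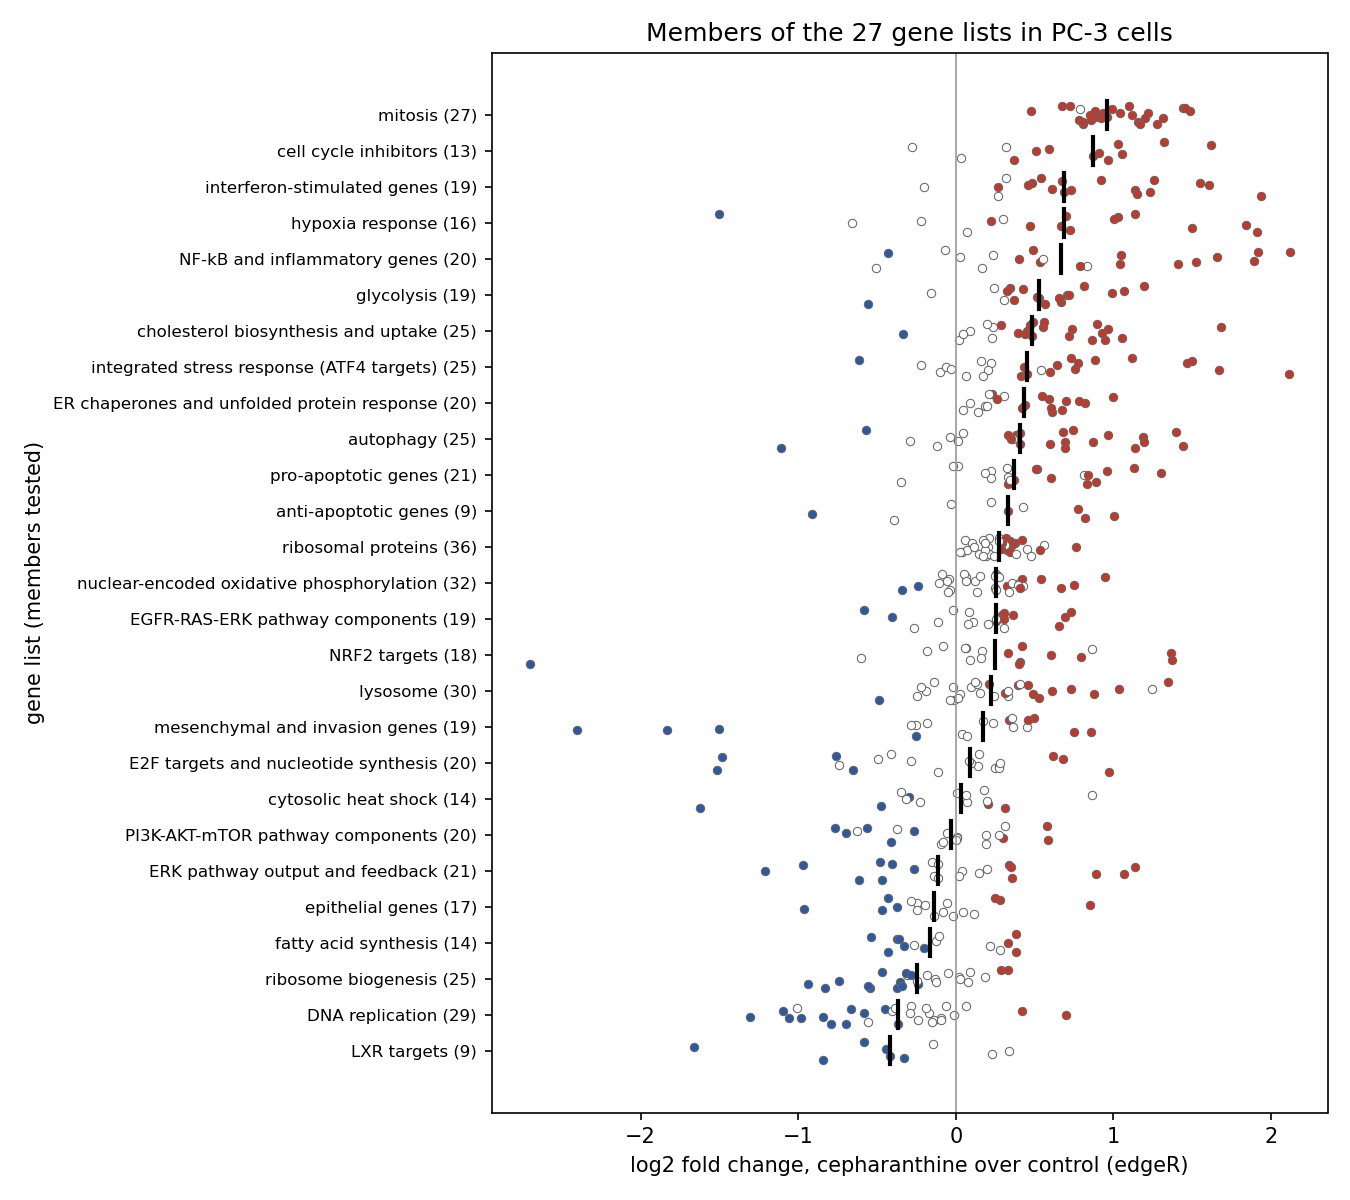
Log2 fold change (horizontal axis, treated over control) of each tested member of the gene lists, which are given on the vertical axis with the number of members tested. Filled red circles passed the test as higher, filled blue circles as lower, open circles did not pass, and the black tick is the list median. The mitosis list has the highest median, 0.96, with 26 of 27 members higher, and the DNA replication list a median of -0.37 with 11 of 29 lower.

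Genes of cholesterol synthesis were higher in treated cells. Of the 25 tested members of the cholesterol list 18 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 4.4e-08, and adjusted p = 0.184 with an estimated correlation). The KEGG steroid biosynthesis pathway, looked up after the list was seen, was called higher, with 9 higher and 1 lower of 19 (camera adjusted p = 0.0485, and adjusted p = 0.440 with an estimated correlation). This pathway may share members with the list. STARD4, a carrier of cholesterol between membranes, rose by a log2 fold change of 1.68 ± 0.13, the mevalonate pathway enzymes MVD by 0.97 ± 0.07 and IDI1 by 0.93 ± 0.08, and the sterol sensor INSIG1 by 0.86 ± 0.07. Among the 9 tested targets of LXR, the oxysterol receptor, 6 fell and 0 rose, the same numbers when adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.228 with an estimated correlation). The cholesterol efflux transporters ABCG1 and ABCA1 fell, with log2 fold changes of -1.66 ± 0.12 and -0.84 ± 0.14. The 6 LXR calls became 3 without control replicate 1, 3 without control replicate 2, 2 without control replicate 3 and 2 without cepharanthine replicate 2. The LXR list call ended without genes that overlap another on the same strand, as ABCG1 does (camera adjusted p = 0.111). The list median was -0.42 in that fit and -0.42 in the main test, so the fall did not shrink. The call also ended in the limma fit of genes with a mean FPKM of at least 5, with a median of -0.09 (camera adjusted p = 0.445). In the limma fits 4 of 8 LXR targets were called lower on FPKM as deposited and 1 after rescaling to TPM. The fatty acid synthesis list did not pass (camera adjusted p = 0.493). Of its 14 members 3 rose and 6 fell, 5 and 7 when adjusted over the list alone, with FASN, the fatty acid synthase, at -0.54 ± 0.13 and the desaturase SCD at 0.38 ± 0.08. Its 6 falls became 2 without control replicate 1, 3 without control replicate 2, cepharanthine replicate 1, 2 or 3, and its median was -0.16. In the limma fits the median of 13 members was -0.06 on FPKM as deposited, with 5 higher and 3 lower, and 0.12 after rescaling to TPM, with 5 higher and 0 lower.

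The fixed lists of lysosomal and autophagy genes were higher, though the broader KEGG lysosome pathway was not. Of 30 lysosomal genes 11 rose and 1 fell, 12 and 3 when adjusted over the list alone (camera adjusted p = 0.00166, and adjusted p = 0.116 with an estimated correlation). Besides NPC1 (1.35 ± 0.07), the luminal cholesterol carrier NPC2 rose by 1.03 ± 0.07, the sialidase NEU1 by 0.88 ± 0.09 and the proton pump subunit ATP6V1C1 by 0.73 ± 0.08. The member that fell was the acid glucosidase GAA (-0.48 ± 0.09), and without control replicate 1 a count of 2 lysosomal genes fell. The lysosome list call ended after quantile normalization of FPKM (camera adjusted p = 0.05003). The KEGG lysosome pathway, looked up after the list was seen, had 25 members higher and 11 lower of 118, a median of 0.02, and was not called (camera adjusted p = 0.332). Of 25 autophagy genes 17 rose and 2 fell, 18 and 2 when adjusted over the list alone (camera adjusted p = 8.7e-06, and adjusted p = 0.116 with an estimated correlation). The KEGG pathway of autophagy in animals was called, with 55 higher and 13 lower of 114 (camera adjusted p = 4.4e-05, and adjusted p = 0.244 with an estimated correlation). Transcripts of the cargo receptors SQSTM1 (1.44 ± 0.07) and OPTN (1.40 ± 0.07) rose, as did those of MAP1LC3B, the membrane-bound LC3 protein (1.19 ± 0.08), and of the phosphoinositide-binding protein WIPI1 (1.19 ± 0.08). ATG12 and ATG16L1, components of the LC3 conjugation machinery, fell (-1.11 ± 0.08 and -0.57 ± 0.09).

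Stress responses of the endoplasmic reticulum and of translation were higher, and the cytosolic heat shock list was not. Of 25 targets of the integrated stress response factor ATF4, 14 rose and 1 fell, 15 and 1 when adjusted over the list alone (camera adjusted p = 8.7e-06, and adjusted p = 0.116 with an estimated correlation). DDIT3 rose by 2.12 ± 0.17, the stress regulator NUPR1 by 1.47 ± 0.08, the mTORC1 inhibitor DDIT4 from 51.6 ± 3.68 to 145 ± 27.7 CPM and PPP1R15A (GADD34), which directs dephosphorylation of eIF2α, by 1.12 ± 0.09. The glutathione-degrading enzyme CHAC1 fell (-0.61 ± 0.12). The KEGG pathway of protein processing in the endoplasmic reticulum, looked up after the lists were seen, was called higher, with 54 higher and 22 lower of 155 (camera adjusted p = 0.00571, and adjusted p = 0.262 with an estimated correlation). Of 20 endoplasmic reticulum chaperone and unfolded protein response genes 13 rose and 0 fell, 16 and 0 when adjusted over the list alone (camera adjusted p = 2.9e-06, and adjusted p = 0.184 with an estimated correlation). HSP90B1 (GRP94) rose by 0.67 ± 0.07, the secreted stress protein MANF by 0.61 ± 0.07 and the lectin chaperone CANX by 0.59 ± 0.08. Of 14 heat shock genes 2 rose and 3 fell, the same numbers when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.814). Its median log2 fold change was 0.04, while its mean of -0.10 and the camera direction were below 0. The fall of BAG3, a co-chaperone of HSP70 (-1.62 ± 0.11), was the largest in that list. The 3 heat shock falls became 1 without control replicate 1, control replicate 2 or any cepharanthine replicate, and the 2 rises became 0 without control replicate 3 and 1 without any cepharanthine replicate. The camera direction of the heat shock list was up without control replicate 1 (camera adjusted p = 0.554) or cepharanthine replicate 1 (camera adjusted p = 0.923).

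Mitotic genes were higher while genes of DNA replication were lower. Of 27 mitosis genes 26 rose and 0 fell, 27 and 0 when adjusted over the list alone (camera adjusted p = 3.8e-17, and adjusted p = 0.116 with an estimated correlation). The mitotic kinesin KIF20A rose by 1.45 ± 0.10, the chromosomal passenger subunit BIRC5 (survivin) by 1.31 ± 0.10, the kinase AURKA by 1.27 ± 0.09 and the checkpoint kinase BUB1B by 0.93 ± 0.07. The proliferation marker MKI67 rose from 65.7 ± 6.42 to 115 ± 20.8 CPM (edgeR adjusted p = 0.00153), and the phosphatase CDC25C missed the threshold (0.79 ± 0.27, edgeR adjusted p = 0.0513). The KEGG cell cycle pathway, which spans all phases and was looked up after the list was seen, had 42 members higher and 20 lower of 121 and was not called (camera adjusted p = 0.0555). Of 29 DNA replication genes 11 fell and 2 rose, 14 and 2 when adjusted over the list alone (camera adjusted p = 1.2e-04, and adjusted p = 0.313 with an estimated correlation). The KEGG pathway of DNA replication was called lower, with 12 lower and 3 higher of 35 (camera adjusted p = 0.0491, and adjusted p = 0.571 with an estimated correlation). It may share members with the list and is not separate support. Helicase subunits MCM3 and MCM4 fell (-1.10 ± 0.10 and -1.06 ± 0.10), as did the catalytic subunits of the replicative polymerases, POLD1 and POLE (-0.84 ± 0.09 and -0.69 ± 0.09). The licensing factor CDC6 and the helicase factor GINS3 rose (0.42 ± 0.11 and 0.70 ± 0.21). These 2 rises became 0 without control replicate 3 and 1 without control replicate 1 or any cepharanthine replicate. In the limma fits the median of 26 replication genes was -0.17 on FPKM as deposited, with 1 higher and 9 lower, and -0.04 after rescaling to TPM, with 2 higher and 5 lower. The list of E2F targets and nucleotide synthesis did not pass (camera adjusted p = 0.812), with 4 members higher and 4 lower of 20, and 4 and 5 when adjusted over the list alone. Its median was 0.09, while its mean of -0.13 and the camera direction were below 0, and the 4 rises became 2 without control replicate 3 or cepharanthine replicate 2. The transcription factor E2F1 fell (-1.49 ± 0.15), as did UHRF1 and DNMT1, which maintain DNA methylation (-1.51 ± 0.11 and -0.65 ± 0.08), while the atypical repressor E2F7 rose (0.97 ± 0.10). Of 13 cell cycle inhibitors 10 rose and 0 fell, the same numbers when adjusted over the list alone (camera adjusted p = 1.8e-05, and adjusted p = 0.116 with an estimated correlation). CDKN1A, which encodes the inhibitor p21, rose from 30.7 ± 2.83 to 76.6 ± 4.76 CPM (1.32 ± 0.09), CDKN2A by 1.03 ± 0.08, GADD45A by 0.91 ± 0.08 and BTG1 by 0.97 ± 0.09.

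**Figure D2:**
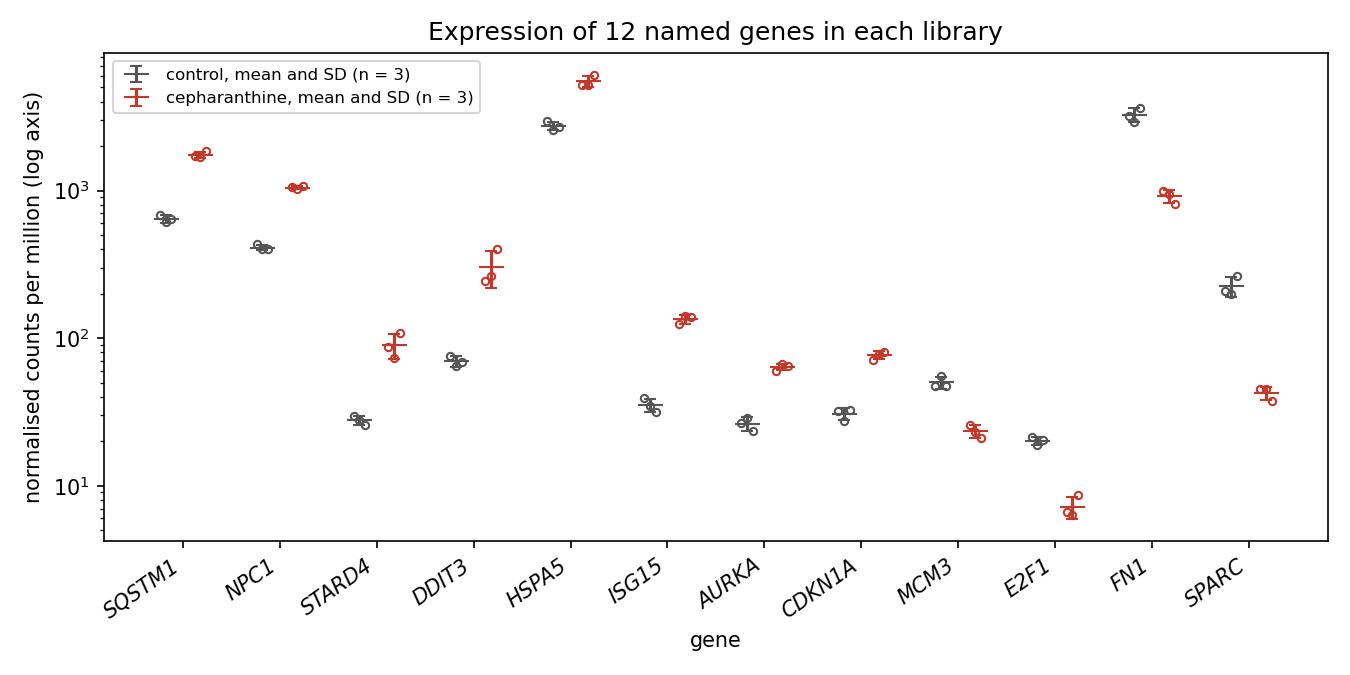
Normalised counts in CPM (vertical, log axis) of 12 genes named in the text, with each library as a circle and the mean and SD (n = 3) of each group as bars. In each of the 12 genes the 3 values of a group lay above the 3 of the other, for example CDKN1A at 30.7 ± 2.83 CPM in control and 76.6 ± 4.76 CPM in treated cells.

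Pro-apoptotic genes were higher, and the shorter anti-apoptotic list, with a similar median, did not pass. Of 21 pro-apoptotic genes 11 rose and 0 fell, 12 and 0 when adjusted over the list alone (camera adjusted p = 1.8e-05, and adjusted p = 0.160 with an estimated correlation), and without control replicate 2 the count was 7. The pro-apoptotic list call ended in the limma fit of genes with a mean FPKM of at least 5 (camera adjusted p = 0.146). Fewer genes were tested there, and the list median was 0.58, against 0.37 in the main test. The KEGG apoptosis pathway, looked up after the list was seen, was called higher, with 38 higher and 14 lower of 120 (camera adjusted p = 0.00401, and adjusted p = 0.262 with an estimated correlation). The BH3-only genes BBC3 (PUMA), BAD and BMF rose, BBC3 from 3.73 ± 0.850 to 9.22 ± 0.777 CPM and the others by 0.96 ± 0.12 and 0.89 ± 0.10, and the death receptor TNFRSF10B (DR5) by 0.51 ± 0.08. Of 9 anti-apoptotic genes 4 rose and 1 fell, 5 and 1 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0917), though it did without cepharanthine replicate 2 (camera adjusted p = 0.0409). Its median was 0.33, close to the 0.37 of the pro-apoptotic list, and fry called it higher (adjusted p = 0.0432). The lists were not tested against each other, so no shift between them is shown. The inhibitors of apoptosis BIRC3, XIAP and BIRC2 rose (1.01 ± 0.12, 0.82 ± 0.11 and 0.77 ± 0.09), while BCL2L1, which encodes BCL-XL, fell from 537 ± 41.1 to 285 ± 38.1 CPM.

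Growth factor signalling lists were mixed. Of 19 components of the EGFR, RAS and ERK pathway 8 rose and 2 fell, 10 and 3 when adjusted over the list alone (camera adjusted p = 0.0461, and adjusted p = 0.184 with an estimated correlation). The kinases RPS6KA3 and MAP2K1 (MEK1) rose (0.69 ± 0.08 and 0.65 ± 0.11), and the receptors ERBB2 and ERBB3 fell (-0.58 ± 0.08 and -0.41 ± 0.08). This list call ended without control replicate 2 (camera adjusted p = 0.0991) or cepharanthine replicate 1 (camera adjusted p = 0.0805), and under the limma fits on filtered FPKM. Its median was 0.25 in the main test, 0.18 and 0.24 without these libraries, and between 0.17 and 0.48 in those limma fits. Its 8 rises became 3 without control replicate 3 or cepharanthine replicate 1 and 4 without cepharanthine replicate 2 or 3. EGFR itself was at 534 ± 37.4 CPM in control and 495 ± 19.99 CPM in treated cells (edgeR adjusted p = 0.322), with a log2 fold change of -0.11 ± 0.08 here, and of -0.05 and 0.13 in the limma fits on FPKM as deposited and rescaled to TPM. MAPK3 (ERK1) did not pass (0.30 ± 0.15, edgeR adjusted p = 0.174). Of 21 ERK output and feedback genes 6 rose and 7 fell, 7 and 7 when adjusted over the list alone (camera adjusted p = 0.814). The phosphatase DUSP1 rose by 1.14 ± 0.15 and the AP-1 subunit JUN by 0.89 ± 0.08, and the feedback inhibitors SPRY1 and SPRY4 fell (-1.21 ± 0.15 and -0.97 ± 0.11). The list median was -0.11, and in the limma fits -0.06 on FPKM as deposited, with 6 of 20 higher and 6 lower, and 0.12 after rescaling to TPM, with 7 higher and 2 lower. Its camera direction was up without control replicate 1 (camera adjusted p = 0.902). Of 20 PI3K, AKT and mTOR components 3 rose and 5 fell, 5 and 6 when adjusted over the list alone (camera adjusted p = 0.767), and the median was -0.03. It was already above 0 in the limma fit on FPKM as deposited (0.05, with 4 of 19 higher and 4 lower) and was 0.22 after rescaling to TPM, with 7 higher and 3 lower. The adaptors IRS1 and RPTOR fell (-0.77 ± 0.11 and -0.56 ± 0.08), and the GTPase RHEB and the transcription factor FOXO3 rose (0.58 ± 0.09 and 0.58 ± 0.10). Among KEGG pathways, looked up after the lists were seen, mTOR signalling was called higher (46 higher and 20 lower of 131, camera adjusted p = 0.0402). ErbB signalling was also called higher (26 higher and 11 lower of 71, camera adjusted p = 0.0409). With an estimated correlation their adjusted p was 0.262 and 0.354. MAPK, Ras and PI3K-Akt signalling were not called (camera adjusted p = 0.0975, 0.107 and 0.724).

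Inflammatory and interferon-stimulated genes were higher in treated cells. Of 20 NF-kB and inflammatory genes 12 rose and 1 fell, 14 and 1 when adjusted over the list alone (camera adjusted p = 4.5e-06, and adjusted p = 0.116 with an estimated correlation). The manganese superoxide dismutase SOD2 rose by 2.12 ± 0.13, the chemokines CXCL8 and CXCL2 by 1.92 ± 0.17 and 1.66 ± 0.08, and the cytokine IL6 by 1.89 ± 0.13, from 8.57 ± 1.11 to 31.9 ± 2.44 CPM. The cytokine IL1B fell (-0.43 ± 0.10). The KEGG pathway of NF-kappa B signalling, looked up after the list was seen, had 21 members higher and 9 lower of 79 and was not called (camera adjusted p = 0.111). Of 19 interferon-stimulated genes 16 rose and 0 fell, 17 and 0 when adjusted over the list alone (camera adjusted p = 4.4e-08, and adjusted p = 0.227 with an estimated correlation). The ubiquitin-like modifier ISG15 rose by 1.94 ± 0.10, IFI6 by 1.61 ± 0.15, and the RNA sensor IFIH1 (MDA5) by 1.23 ± 0.10. The 3 members that did not pass were OAS1 (0.32 ± 0.11), DDX58, which encodes the RNA sensor RIG-I (0.27 ± 0.13), and IFIT2 (-0.20 ± 0.27).

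The fixed lists of glycolytic and hypoxia-response genes were higher, and transcripts of the mitochondrial genome were lower. Of 19 glycolysis genes 15 rose and 1 fell, 17 and 2 when adjusted over the list alone (camera adjusted p = 1.0e-06, and adjusted p = 0.116 with an estimated correlation). GAPDH rose from 1246 ± 95.9 to 2482 ± 135 CPM, the aldolase ALDOC by 1.07 ± 0.08, the enolase ENO2 by 1.20 ± 0.10 and TPI1 by 0.72 ± 0.07, and the phosphofructokinase PFKM fell (-0.56 ± 0.08). Of 16 hypoxia-response genes 11 rose and 1 fell, 12 and 1 when adjusted over the list alone (camera adjusted p = 6.6e-05, and adjusted p = 0.194 with an estimated correlation). The peptide hormone gene ADM rose by 1.91 ± 0.09, NDRG1 by 1.84 ± 0.09, from 988 ± 93.3 to 3535 ± 223 CPM, and the mitophagy receptor BNIP3, which is also in the autophagy list, by 1.14 ± 0.09. The KEGG pathways of glycolysis and gluconeogenesis (22 higher and 9 lower of 53, camera adjusted p = 0.170) and of HIF-1 signalling (28 higher and 15 lower of 84, camera adjusted p = 0.0691), looked up after the lists were seen, were not called. All 13 messenger RNAs of the mitochondrial genome fell, by log2 fold changes from -0.72 (MT-ND1) to -1.40 (MT-CO3). Mitochondrially encoded genes held 10.9 ± 1.86% of the counts in control and 5.99 ± 0.985% in treated libraries (SD, n = 3 per group; exact two-sided permutation p = 0.1, the smallest possible). Of the 13 falls 6 were called after quantile normalization of FPKM, where their median was -0.21. On FPKM without a filter 2 were called, though their median was -1.04. Of 32 nuclear-encoded genes of oxidative phosphorylation 7 rose and 2 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.0201, and adjusted p = 0.669 with an estimated correlation). The KEGG pathway of oxidative phosphorylation was called higher, with 35 higher and 21 lower of 126 (camera adjusted p = 0.0485, and adjusted p = 0.573 with an estimated correlation). It is a broader set, from which mitochondrially encoded genes were not left out, so it does not measure the nuclear-encoded genes alone. Fry called neither the list (adjusted p = 0.242) nor the pathway (adjusted p = 0.0599). The complex I subunit NDUFV2 rose (0.54 ± 0.09), and cytochrome c1, CYC1, and the succinate dehydrogenase subunit SDHA fell (-0.34 ± 0.07 and -0.24 ± 0.07). This list call ended without control replicate 1 (camera adjusted p = 0.0826), control replicate 3 (0.102) or cepharanthine replicate 3 (0.0701), and under the limma fits on filtered FPKM. Its median was 0.25 in the main test, 0.16, 0.20 and 0.16 without these libraries, and between 0.17 and 0.49 in those limma fits. Its 7 rises became 1 without control replicate 1 or 3, 2 without cepharanthine replicate 2 or 3, and 13 without control replicate 2, and its 2 falls became 1 without any library other than control replicate 2. Of 18 NRF2 targets 8 rose and 1 fell, 10 and 1 when adjusted over the list alone (camera adjusted p = 0.0062, and adjusted p = 0.117 with an estimated correlation), with 5 rises without control replicate 3 and 2 falls without cepharanthine replicate 2. The NRF2 list call ended without genes that overlap another on the same strand (camera adjusted p = 0.0700), with a median of 0.16 against 0.25 in the main test. The ferritin chains FTH1 and FTL rose (1.37 ± 0.09 and 1.37 ± 0.10), with FTH1 going from 6335 ± 522 to 16331 ± 1356 CPM, and the glutathione synthesis enzyme GCLC rose by 0.61 ± 0.07. The aldo-keto reductase AKR1B10 fell (-2.70 ± 0.32).

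The mesenchymal and epithelial lists had no common direction, and the matrix genes SPARC and FN1 were among the falls. Of 19 mesenchymal and invasion genes 5 rose and 4 fell, 5 and 5 when adjusted over the list alone (camera adjusted p = 0.814). The median of that list was 0.17 and its camera direction was up, while its mean was -0.11 and its fry direction was down. The camera direction was also down without control replicate 2 (camera adjusted p = 0.937) or cepharanthine replicate 2 (camera adjusted p = 0.894). The secreted matrix proteins SPARC and FN1 fell (-2.40 ± 0.12 and -1.83 ± 0.10), and the intermediate filament protein VIM rose (0.75 ± 0.09). Of 17 epithelial genes 3 rose and 4 fell, 3 and 5 when adjusted over the list alone (camera adjusted p = 0.263). The tight junction protein OCLN rose (0.85 ± 0.10), and the keratin KRT7, the transcription factor GRHL2 and the adhesion molecule EPCAM fell (-0.47 ± 0.08, -0.96 ± 0.18 and -0.37 ± 0.07). The 3 epithelial rises became 1 without cepharanthine replicate 2, and the list median was -0.14. In the limma fits the median of 16 epithelial genes was -0.06 on FPKM as deposited, with 3 higher and 3 lower, and 0.12 after rescaling to TPM, with 5 higher and 0 lower. Some markers of other cell types fell, and others did not pass the test. Of 6 tested fibroblast markers 2 fell, COL3A1 from 44.8 ± 2.77 to 12.6 ± 1.75 CPM and COL1A1 from 90.2 ± 10.3 to 56.6 ± 4.62 CPM, and both tested endothelial markers fell, PECAM1 from 46.5 ± 2.46 to 20.96 ± 3.18 CPM and KDR from 14.5 ± 1.88 to 6.73 ± 1.28 CPM. Of 5 leukocyte markers 0 passed the test, and of 3 neuroendocrine markers 1 rose, ENO2, which is also in the glycolysis list.

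Listed ribosomal protein genes were higher and listed ribosome assembly genes lower, though a broader assembly pathway had no direction. Of 36 ribosomal protein genes 12 rose and 0 fell, 14 and 0 when adjusted over the list alone (camera adjusted p = 7.4e-05, and adjusted p = 0.524 with an estimated correlation), with RPS9 at 0.53 ± 0.12 and RPLP0 at 0.42 ± 0.08. The count was 6 without control replicate 1, 20 without control replicate 2, 5 without control replicate 3 and 6 without cepharanthine replicate 2, and fry did not call the list (adjusted p = 0.0821). Of 25 ribosome biogenesis genes 12 fell and 2 rose, 13 and 2 when adjusted over the list alone (camera adjusted p = 0.0049, and adjusted p = 0.316 with an estimated correlation). POLR1A, the largest subunit of RNA polymerase I, fell, with a log2 fold change of -0.94 ± 0.09, and the assembly factors UTP20, RRS1 and NOP2 fell (-0.83 ± 0.08, -0.74 ± 0.12 and -0.54 ± 0.10). The nucleolar proteins NPM1 and FBL rose (0.33 ± 0.08 and 0.29 ± 0.09), a count that became 1 without control replicate 1 or 3 or cepharanthine replicate 1 or 2. Among ribosomal proteins, the KEGG ribosome pathway was called higher, with 41 higher and 2 lower of 130 (camera adjusted p = 4.4e-05, and adjusted p = 0.551 with an estimated correlation). The KEGG pathway of ribosome biogenesis, looked up after the list was seen, had 16 members higher and 16 lower of 74, a median of 0.01, and was not called (camera adjusted p = 0.914). The biogenesis list call ended without genes that overlap another on the same strand, as RRS1 and NOP2 do (camera adjusted p = 0.159). The list median was -0.19 in that fit, with fewer members tested, and -0.24 in the main test. In the limma fits the median of the biogenesis list was -0.18 on FPKM as deposited, with 2 members higher and 7 lower, and -0.01 after rescaling to TPM, with 4 higher and 3 lower.

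Some genes of prostate identity fell. The protease TMPRSS2, the transporter SLC45A3 and the homeobox factor HOXB13 fell (-0.67 ± 0.08, -0.66 ± 0.09 and -0.66 ± 0.10). Of 4 nuclear-retained RNAs, a sign of nuclear RNA content, 1 rose, KCNQ1OT1 (0.28 ± 0.08), while NEAT1 and MALAT1 did not pass (0.14 ± 0.10 and 0.07 ± 0.11).

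The largest changes of single genes included HGF, the ligand of the MET receptor, which rose from 1.82 ± 0.116 to 19.7 ± 3.05 CPM, a log2 fold change of 3.44 ± 0.17 (edgeR adjusted p = 2.6e-06). HGF (ENSG00000019991) lies on chromosome 7 from 81699010 to 81770398. ATP6V0D2, a proton pump subunit, had 4, 35 and 0 counts in control and 472, 308 and 647 in treated libraries, a log2 fold change of 5.04 ± 0.75 that became 7.56 without control replicate 2. The long non-coding RNA GAPLINC rose from 14, 0 and 22 counts to 124, 131 and 149. Against a floor of 3 counts over the control group, ELOCP2 was at least 77.5-fold higher, the carbonic anhydrase CA7 at least 20.9-fold, PRR32 at least 19.3-fold and the protocadherin PCDHA1 at least 18.4-fold. ISY1-RAB43, a readthrough gene of ISY1 and RAB43, had 1723, 1768 and 1038 counts in control libraries and 0 in every treated library, at least 1617-fold lower. It (ENSG00000261796) lies on the minus strand of chromosome 3 from 129087575 to 129161036 and overlaps ISY1 and RAB43 on the same strand. Counts assigned to ISY1 were higher in treated cells by a log2 fold change of 1.38 ± 0.13 and those assigned to RAB43 went from 16.9 ± 3.46 to 47.7 ± 0.896 CPM, while the summed counts of the 3 genes rose by only 0.39 ± 0.08, so all 3 values are uncertain. Genes at 0 in every treated library also included the meiotic helicase HFM1 (at least 73.9-fold lower), the trypsinogen PRSS1 (at least 44.6-fold), the arginine deiminase PADI4 (at least 38.6-fold), the ephrin receptor EPHB1 (at least 17.1-fold) and the homeobox gene NKX1-2 (at least 13.6-fold). Counts of the trypsinogen PRSS2 fell from 261, 161 and 287 to 0, 7 and 21, and those of the cytokine IL16 from 75, 80 and 18 to 4, 0 and 0, and of the calpain CAPN13 from 14, 15 and 18 to 0, 0 and 1. The log2 fold change of IL16 was -5.42 ± 1.04, and -8.90 without cepharanthine replicate 1.

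The calls of SLAMF7, HRH4, SAR1AP1, DDX59-AS1 and RPL12P38 among the rises and of AQP5, ELOCP18 and FGF20 among the falls rested on few counts. Each was lost without some of the libraries. The rises of HRH4, SAR1AP1 and DDX59-AS1 were lost without any library other than control replicate 2, with edgeR adjusted p up to 0.110, 0.157 and 0.118. That of SLAMF7 was lost without control replicate 1 or 3 or cepharanthine replicate 1 or 3 (edgeR adjusted p up to 0.0664), and that of RPL12P38 without any library other than control replicate 1 (up to 0.120). AQP5 lost its call without control replicate 3 or cepharanthine replicate 1 or 3 (edgeR adjusted p up to 0.125), ELOCP18 without control replicate 2 or 3 or cepharanthine replicate 1 or 2 (up to 0.0815), and FGF20 without control replicate 1 or cepharanthine replicate 2 (up to 0.0669).

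**Figure D3:**
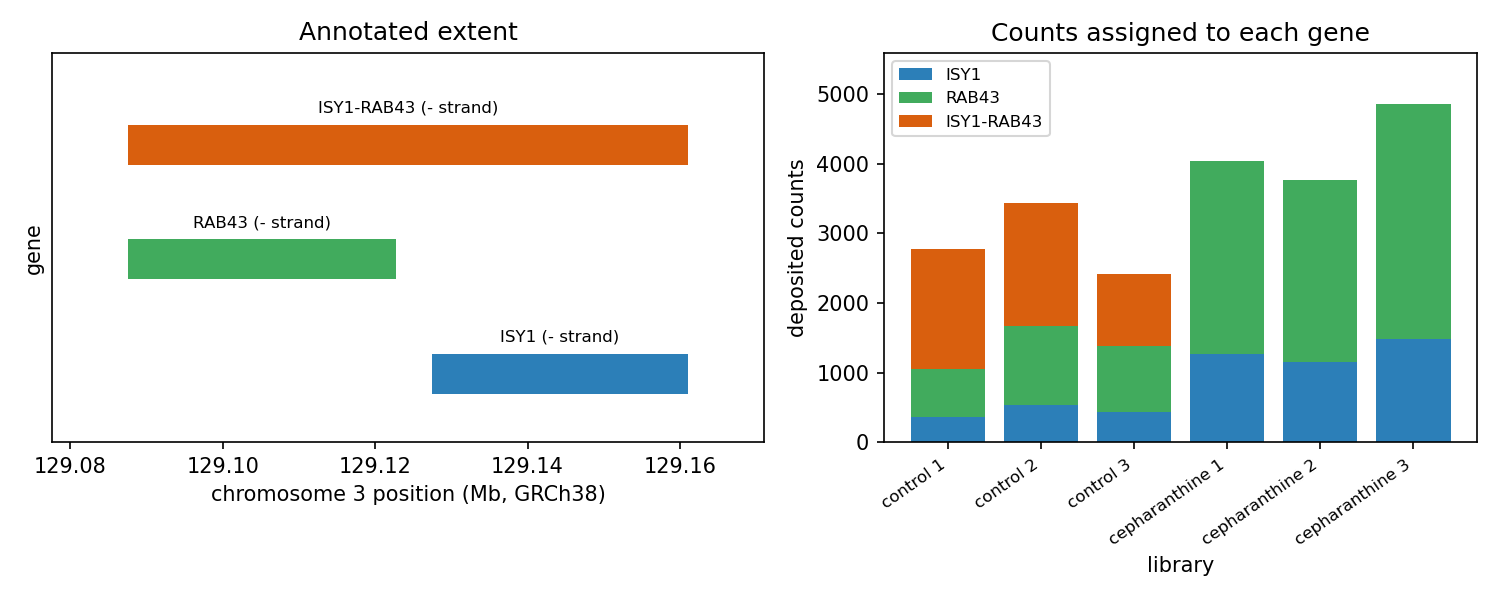
Extent of ISY1, RAB43 and ISY1-RAB43 along chromosome 3 (left, horizontal axis in Mb of GRCh38) and the deposited counts assigned to each gene in every library (right, stacked bars from 0). ISY1-RAB43 holds 1038 to 1768 counts in the control libraries and 0 in the treated libraries, and the 3 genes sum to 2423 to 3433 counts in control and 3765 to 4857 in treated libraries.

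Reads of overlapping genes may be split by the counting, whose use of strand is not given in the sources used here. Of the 6121 genes called, 3040 overlap a gene on the opposite strand and 1678 overlap a gene on the same strand. Of the 135 genes given by the rule, 61 overlap a gene on the opposite strand and 27 overlap a gene on the same strand. Those of the latter described above, with ISY1, RAB43 and COL3A1, are uncertain for that reason: PCDHA1, ISY1-RAB43, SOD2, WIPI1, NPC2, DDIT3, GCLC, BTG1, BUB1B, ABCG1, ALDOC, ENO2, DNMT1, HSP90B1, CANX, RRS1, NOP2, BBC3, ERBB2, KRT7 and EPCAM. If the counting ignored strand, the genes that overlap another on the opposite strand are uncertain too. Among them are SQSTM1, NPC1, FTH1, GAPDH, CDKN1A, IL6, ISG15 and EGFR. Genes with near-identical copies, such as FTH1, GAPDH, the ribosomal protein genes, PRSS1, PRSS2, and the pseudogenes ELOCP2, SAR1AP1, RPL12P38 and ELOCP18, are uncertain as well.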

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

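Named genes kept their direction and side of the threshold in 2488 cases over all alternatives, were weaker in 131, stronger in 1 and reversed in 1. Lists did so in 549 cases, were weaker in 49, stronger in 4 and reversed in 19, where the direction is that of the camera or fry test. Most named genes were picked for a large change or a small adjusted p in these same libraries, so their stability is partly built in. A named gene absent from a fit was not counted for it. DESeq2 called 3610 genes higher and 3271 lower, edgeR with RLE factors 3205 and 2897, and edgeR without a filter 2845 and 2340. For the changes below the cause was not tested, unless stated. The depth limits genes with few counts, and 3 libraries a group limit changes below 2 times. The simulation, with far fewer changed genes than were called here, recovered less of these.

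Requiring an absolute log2 fold change of at least 1 left 478 genes higher and 777 lower, fewer by construction. Camera with an estimated correlation gave adjusted p = 0.116 for lysosome, autophagy, integrated stress response, mitosis, cell cycle inhibitors, NF-kB and inflammatory genes and glycolysis, 0.117 for NRF2 targets, 0.160 for pro-apoptotic genes, 0.184 for cholesterol biosynthesis, endoplasmic reticulum chaperones and EGFR-RAS-ERK components, 0.194 for hypoxia, 0.227 for interferon-stimulated genes, 0.228 for LXR targets, 0.313 for DNA replication, 0.316 for ribosome biogenesis, 0.524 for ribosomal proteins and 0.669 for nuclear-encoded oxidative phosphorylation. Fry gave adjusted p = 0.0227 for E2F targets and 0.0432 for anti-apoptotic genes, which passed, and 0.242 for oxidative phosphorylation and 0.0821 for ribosomal proteins, which did not, with the mesenchymal list reversed (0.288). Without a low-count filter the anti-apoptotic list passed (camera adjusted p = 0.0469).

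The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at 0.00359, -0.00693 and -0.0700. Not every library correlated best with its own number. With a replicate block 2544 genes were higher and 2294 lower, and the EGFR-RAS-ERK list had adjusted p = 0.0600.

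On FPKM, limma called 1897 genes lower on log2(FPKM + 1), 1883 with a pseudocount of 0.1, 1888 with 0.5 and 1899 without trend. In these 4 fits adjusted p of the EGFR-RAS-ERK list was 0.148, 0.150, 0.150 and 0.148, of oxidative phosphorylation 0.0948, 0.114, 0.103 and 0.0948, and of the mesenchymal list, reversed, 0.577, 0.581, 0.585 and 0.577. Without a filter 2077 genes were higher and 1333 lower, and the heat shock list was reversed (0.945). In that fit 2 mitochondrially encoded messenger RNAs were called, though their median was -1.04. With a mean FPKM of at least 5, where fewer genes are tested, 1056 genes were lower, and adjusted p was 0.445 for LXR targets, 0.146 for pro-apoptotic genes, 0.343 for EGFR-RAS-ERK, 0.266 for oxidative phosphorylation, and, reversed, 0.402 for E2F targets and 0.201 for the mesenchymal list. With median-ratio scaling it was 0.174 for EGFR-RAS-ERK, 0.0983 for oxidative phosphorylation, and, reversed, 0.914 for E2F targets and 0.664 for the mesenchymal list. After quantile normalization 6 mitochondrially encoded messenger RNAs were called, and adjusted p was 0.05003 for lysosome, which missed the threshold, 0.275 for EGFR-RAS-ERK, 0.248 for oxidative phosphorylation, and, reversed, 0.806 for E2F targets and 0.515 for the mesenchymal list. After rescaling to TPM 4928 genes were higher and 976 lower, with 0.0999 for EGFR-RAS-ERK, 0.133 for oxidative phosphorylation and, reversed, 0.522 for the mesenchymal list, and the log2 fold change of EGFR reversed to 0.13.

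Without genes that overlap another on the same strand, 8 mitochondrially encoded messenger RNAs were called, as only 8 were left to test. Adjusted p was then 0.111 for LXR targets, 0.0700 for NRF2 targets, 0.159 for ribosome biogenesis and, reversed, 0.977 for heat shock, with fewer members tested. Leaving out each library in turn gave 2392 to 3094 genes higher, 2120 to 2607 lower and 11 to 13 mitochondrially encoded messenger RNAs lower. Adjusted p then ranged from 0.000400 to 0.102 for oxidative phosphorylation, 0.0275 to 0.0991 for EGFR-RAS-ERK, 0.0409 to 0.242 for anti-apoptotic genes, 0.494 to 0.923 for heat shock, 0.655 to 0.923 for ERK output and 0.654 to 0.937 for the mesenchymal list.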

Other observations

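The genes and pathways of this and the next paragraph were chosen after their values were seen. Transcripts of the proteasome were higher in treated cells: of 42 tested members of the KEGG pathway in the deposited annotation 25 rose and 1 fell (camera adjusted p = 2.7e-05 over 307 pathways, and adjusted p = 0.423 with an estimated correlation). The mitophagy pathway also moved up, with 32 of 63 members higher and 5 lower (camera adjusted p = 1.0e-05, and adjusted p = 0.244 with an estimated correlation). Extracellular matrix genes fell beyond FN1 and SPARC. In the pathway of receptor interaction with the extracellular matrix 31 of 65 members fell and 6 rose (camera adjusted p = 0.000137, and adjusted p = 0.262 with an estimated correlation), and 8 of its 13 collagen genes fell and 0 rose. The basement membrane collagens COL4A1 and COL4A2 fell (-1.50 ± 0.11 and -1.31 ± 0.08), as did the cartilage collagen COL2A1, from 19.4 ± 3.43 to 2.87 ± 0.821 CPM. Of the 307 pathways camera called 75 with the preset correlation, 64 higher and 11 lower, and 0 with an estimated correlation.

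Single genes, some picked for large changes and none with a test of its family, included mucins. MUC2 fell from 50.5 ± 11.6 to 10.1 ± 1.84 CPM and MUC6 from 37.4 ± 11.9 to 4.11 ± 0.645 CPM, and the carcinoembryonic antigen genes CEACAM5 and CEACAM6 from 31.2 ± 7.26 to 3.92 ± 0.926 CPM and from 97.9 ± 14.2 to 18.9 ± 2.83 CPM. The metallothionein genes MT2A and MT1X, whose products bind zinc and copper, rose, MT2A from 77.1 ± 5.01 to 225 ± 19.3 CPM and MT1X by 1.27 ± 0.16. The YAP targets CCN1 and CCN2 fell (-0.80 ± 0.14 and -1.11 ± 0.13). The transferrin receptor TFRC, whose messenger RNA falls when iron is plentiful, fell (-0.37 ± 0.11) while the ferritin chains rose. Of 11 tested FTH1 pseudogenes 9 rose and 0 fell, with a median of 1.42, which reads of FTH1 itself can produce.

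In what follows the tests of mitosis, of the mitochondrial transcription machinery and of the splits were written before their values were seen, and those of mitochondrial ribosomal RNA and of overlapping genes after.

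The mitosis list was called higher and the DNA replication list lower, with 11 of 29 replication genes lower and 2 higher, and neither list was called with an estimated correlation (adjusted p = 0.116 and 0.313). In the limma fits the replication median was -0.17 on FPKM as deposited and -0.04 after rescaling to TPM. Gene length or GC content does not account for the mitotic rise: the medians of 10000 lists matched on length, GC content and expression had 0.28 as the upper end of their 95% interval, against 0.96 for mitosis. A lower share of cells in S phase with more in G2 or M predicts a fall of replication-dependent histone transcripts. That fall was not seen: their median was 0.61, with 21 of 46 higher and 1 lower. Histone transcripts mostly lack poly(A) tails and are poorly captured by such libraries, and CDKN1A rose alongside, so where the cells stood in the cycle was not settled by these values.

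Transcripts of the mitochondrial genome fell in all 13 messenger RNAs. Lower recovery of every mitochondrial RNA alike predicts equal falls, and the 2 ribosomal RNAs differed on this. MT-RNR2 lay 0.50 above the median of -1.10 on the log2 scale (-0.61, SE 0.14), more than 2 SE away, while MT-RNR1 at -0.91 (SE 0.11) lay within 2 SE of it, so this explanation is left open. Lower expression of the mitochondrial transcription machinery was not seen at the transcript level, with a median of 0.0161 and 0 of 9 genes past the threshold. Protein levels of that machinery, RNA decay and the number of mitochondrial genomes were not measured.

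Some genes stood at 0 in some libraries and were well counted in others. Of 75 such genes 62 overlapped a gene on the same strand, against 4506 of 15232 other expressed genes, an odds ratio of 11.3 (95% interval 6.17 to 22.5, Fisher's exact p = 3.0e-21). The summed counts of ISY1, RAB43 and ISY1-RAB43 rose by 0.39 with an SE of 0.08 (edgeR adjusted p = 0.00575). The zero of ISY1-RAB43 therefore does not show a loss of transcription of the locus. Reads moved between the 3 genes by the counting would leave the sum without a fall. So would a change from the readthrough transcript to separate transcripts, and the sum cannot tell these apart. Of the 75 genes 10 were called, 3 higher and 7 lower.

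The number of genes past the threshold was set against the other ways to divide the 6 libraries into 3 and 3. Of 10 such divisions 1, the real one, gave 6121 calls, and the highest of the others gave 0. Each of the other 9 mixes treated and control libraries in both groups. Differences between treated and control libraries then add to the spread within groups, so few calls were to be expected there. So few divisions cannot by themselves exclude chance.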
